A study of Arabidopsis thaliana with 7 samples.

How the data were processed

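ChIP-seq peak lists of GFP-tagged CCA1 from Arabidopsis thaliana seedlings (WS-2 ecotype) were analysed for 2 light regimes, continuous light (LL, 3 libraries) and light-dark cycles (LD, 2 libraries), all harvested at ZT2. Per the labels' protocols, 14-day-old whole seedlings were fixed with 1% formaldehyde for 20 min, and sonicated chromatin was precipitated with anti-GFP, with IgG or input material as controls. The LL library of ZT14 and the input DNA library had no list of their own and were not analysed here. Groups were taken from the labels of each sample.

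Per the submitters' processing notes, CASAVA 1.8, Trimmomatic 0.33, Bowtie2 2.2.1 and HOMER 4.7 were used with the TAIR10 genome. Per the file headers, the deposited peaks came from HOMER's findPeaks and form the top set of an irreproducible discovery rate (IDR) step on the combined data of a regime. Whether duplicates were removed, the IDR threshold and which library served as control are not given in the sources used here. Because the deposited lists pool replicates, no replicate could be compared or left out. For each peak the authors gave a count of total tags, a normalised tag count (a signal scaled by 1 constant per list), a count of control tags scaled to the precipitated library (also a signal), a score, a fold ratio over control, a clonal fold, and p-values over control, per the file headers. The lowest fold over control was 4.01 in LL and 4.08 in LD. The score and fold of a peak were used to describe, rank or filter peaks within its own list, and the scores of shared peaks were also correlated between the lists. Per the file headers, the authors annotated the peaks with HOMER's annotatePeaks.pl and the tair10 genome. Per the file headers, this gave the genomic category, the distance from the peak centre to the nearest TSS, the nearest promoter's gene and the GC fraction of a 500 bp window. The deposited columns held 0 per-sample values left unused.

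The constant between normalised and total tags was 7.48 in LL and 3.44 in LD. The total number of tags behind each list is not given in the sources used here. Tags per peak carry counting error, given as exact 95% Poisson intervals. Shares carry 95% Wilson intervals. Both cover counting error only, since tags amplified by PCR are not independent molecules. Peaks and genes are the units of every test, and they are neither biological replicates nor independent of each other, so the p-values say nothing on the spread between plants.

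Peaks were called shared when they overlapped by at least 1 bp. The number of shared peaks was set against 1000 circular shifts of the LD peaks along their chromosomes, one-sided. The planned null, which keeps the distance to the TSS, needs gene strands and was not run. Shared genes, genomic categories and gene lists were tested with 2-sided Fisher's exact tests. Differences in medians and correlations were tested with 100000 permutations. Adjustment was by Benjamini-Hochberg. At shared genes, the distance of the highest peak to the TSS was compared between the lists and with 10000 random pairings. Gene names and the universe of 37899 nuclear genes (27444 protein-coding) came from a RefSeq gene table of assembly TAIR10.1 (GCF_000001735.4), of which no coordinates were used. Of the 1760 nearest-gene identifiers in either list, 1726 matched it, and all 225 members of the gene lists did. Nearest-gene assignment favours genes with long upstream regions, and no background matched on that length was available. Among peaks whose annotation column names a gene, that gene differed from the nearest promoter's gene for 197 of 1162 (17.0%) in LL and 210 of 1296 (16.2%) in LD.

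Before the data were examined, 14 gene lists, the tests, the alternatives and the rule for named genes were fixed. Named were the nearest genes of the 10 highest peaks of each list, those of the 5 highest unshared peaks of each list, and the list members with a peak. Scores were given for up to 4 members per list in order of LL score, then LD score, and for CCA1. Scores of further genes named as bound in a single regime, of GI, of EF1A and of a further CDF1 peak, the genes COL5 and COL9, the distances between peaks at TIC, COR413PM1 and PHS2, and the peaks beside PRR7, PRR9 and GI in the annotation column, were chosen after the values were seen. The alternatives fixed then were the upper 50% of each list by score, the same number of peaks from both lists, an overlap of 50% of both peaks, peak centres within 500 bp, genes with a peak from 1000 bp upstream to 500 bp downstream of the TSS, a protein-coding background, and lists without organelle peaks. Chosen after the data were seen were the gene of the annotation column, lists without peaks beside rRNA genes, tRNA genes and pseudogenes, total tags in place of the score, the circular shift as the main null, and a test of GC content. Peaks beside rRNA genes, tRNA genes or pseudogenes are those whose nearest gene was of that type, at any distance. Searches for the evening element and related motifs were planned and not run, since no genome sequence was used here.

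The enrichment step was tested on simulated data at the size of the LL gene set. With no enrichment, 3 of 100 draws gave any list past the threshold among 37899 genes. A list of 20 genes with 5 added members was recovered in 100 of 100 draws. Genes were drawn with equal chance from all nuclear genes, so these draws do not test the bias of nearest-gene assignment. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.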

Results

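Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate CCA1 on the genome of Arabidopsis thaliana. CCA1 is a MYB-related transcription factor of the plant circadian clock whose level peaks around dawn. It was tagged with green fluorescent protein (GFP), expressed from its own promoter in the WS-2 ecotype and precipitated with an antibody against GFP. Whole 14-day-old seedlings grown in cycles of 12 h light and 12 h dark were harvested at zeitgeber time (ZT) 2, which is 2 h after dawn or subjective dawn. They were either kept in those cycles (LD, 2 libraries) or moved to continuous light (LL, 3 libraries). A further LL library taken at ZT14 and an input DNA library were not analysed here. Each light regime was represented by a single list of peaks made from its pooled libraries, so no value below has a spread between replicates. The LL list held 1433 peaks of 158 bp with 17 to 229 sequence tags each (median 26). The LD list held 1607 peaks of 124 bp with 31 to 234 tags each (median 46). A tag carried 7.48 normalised units in LL and 3.44 in LD, so the LD data held 2.17 times as many tags if both lists were scaled to the same total, which is not stated. Coordinates are on TAIR10, and peak scores, folds over control and gene assignments are the authors' own values.

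In continuous light the genes of the 10 highest scores included JMJD5, COR27, FKF1 and TOC1, which belong to lists of clock genes fixed beforehand. The peak with the highest score (181) lay on chromosome 2 from 9266517 to 9266675, 203 bp upstream of the transcription start site (TSS) of GRP7 (AT2G21660), a clock-regulated RNA-binding protein. It held 229 tags (95% Poisson interval 200 to 261) and was 58.5-fold over control. The aquaporin gene PIP1C (AT1G01620) carried a peak of score 155 in exon 2 of 4, on chromosome 1 from 226414 to 226572. The histone demethylase gene JMJD5 (AT3G20810; score 140, 25 bp upstream), COR27 (AT5G42900; score 131, 107 bp upstream) and the blue-light receptor gene FKF1 (AT1G68050; score 130, 225 bp upstream) followed. The B-box gene BBX8 (AT5G48250) and the core clock gene TOC1 (AT5G61380) both had a score of 128, at 387 bp and 274 bp upstream of the TSS. The calcium pump gene ACA8 (AT5G57110; intron 1 of 34) and the desaturase gene SLD1 (AT3G61580; 806 bp upstream) both scored 126. The remaining peak among the 10 highest scores (158) lay near the start of chromosome 2, from 9971 to 10129, beside AT2G01023, which encodes a hypothetical protein. It held 18.3 control tags, against 1.5 to 3.9 at the other 9 peaks.

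In the light-dark cycle GRP7 and PIP1C were again among the 3 highest scores, with 236 and 217. The GRP7 peak held 231 tags (95% Poisson interval 202 to 263), 32.9-fold over control. The highest LD score (238) belonged to the peak beside AT2G01023, which had 38.3 control tags and was 6.11-fold over control. The other peaks among the 10 highest held 2.1 to 7.2 control tags. The rank of the AT2G01023 peak may therefore not reflect binding by CCA1 alone, which was not tested. ACA8 scored 194, as did AT1G78995 (139 bp upstream) and AT1G70420 (1052 bp upstream), which both encode hypothetical proteins. The cold-response regulator CBF1 (AT4G25490) carried a peak of score 191 on chromosome 4 from 13023423 to 13023547, 760 bp upstream of its TSS. AT3G51400 (score 188), the chloroplast cytochrome c biogenesis gene CcdA (AT5G54290; score 185) and COR28 (AT4G33980; score 183, 1204 bp upstream) completed the 10 highest scores. Each of the 10 highest peaks of either list overlapped a peak of the other list.

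CCA1 lay mostly just upstream of genes in both regimes. The promoter-TSS category took 851 LL peaks (59.4%, 95% Wilson interval 56.8 to 61.9) and 948 LD peaks (59.0%, 56.6 to 61.4). Intergenic peaks followed with 271 (18.9%) and 311 (19.4%), and peaks at transcription termination sites with 213 (14.9%) and 225 (14.0%). Introns held 55 and 62 peaks and exons 28 and 39. The peak centre was upstream of the nearest TSS for 1029 LL peaks (71.8%) and 1112 LD peaks (69.2%). It lay within 1000 bp of the TSS for 918 LL peaks (64.1%) and 1028 LD peaks (64.0%). The median absolute distance to the TSS was 566 bp in LL and 538 bp in LD. The fullest 100 bp interval was the one directly upstream of the TSS, with 190 LL peaks (13.3%) and 225 LD peaks (14.0%). The nearest gene was protein-coding for 1331 LL peaks and 1503 LD peaks.

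**Figure D1:**
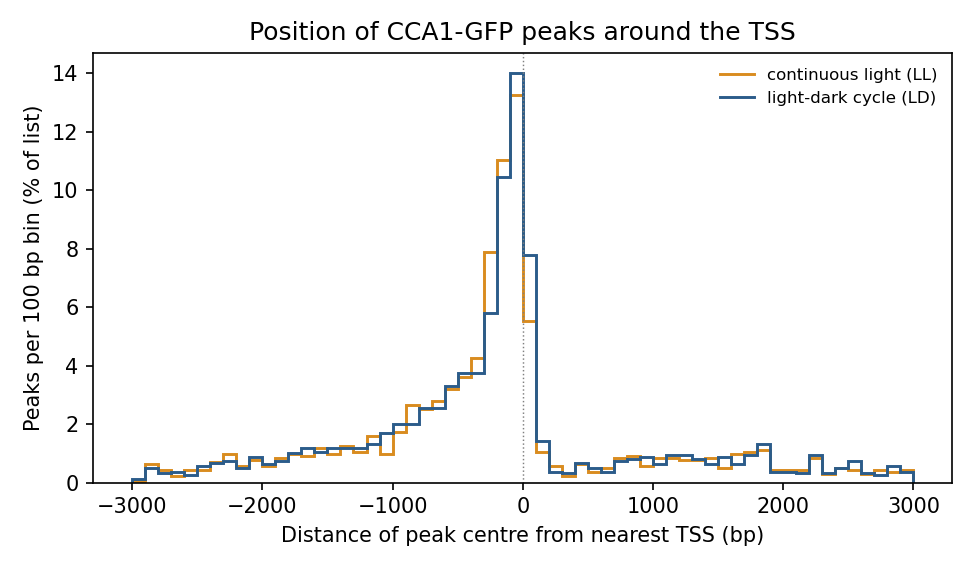
Position of peak centres relative to the nearest TSS, in bins of 100 bp, as a percentage of all peaks in each list (LL orange, LD blue); negative distances are upstream. Both lists are highest directly upstream of the TSS (13.3% of LL and 14.0% of LD peaks), and 115 LL and 117 LD peaks lie outside the plotted range.

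The series set CCA1 binding in continuous light against binding under diel cycles. Most binding sites were found in both regimes: 1069 of the 1433 LL peaks (74.6%, 95% Wilson interval 72.3 to 76.8) overlapped an LD peak by at least 1 bp. These were 66.5% (64.2 to 68.8) of the 1607 LD peaks. Peaks of LD shifted around their chromosomes at random overlapped 5.45 LL peaks on average and at most 14 in 1000 draws (one-sided permutation p = 0.001, the smallest these draws can give). The shifts do not keep the closeness of peaks to the TSS, so this chance level is likely too low. The nearest genes numbered 1306 in LL and 1455 in LD, of which 1001 were shared. Among the 37899 nuclear genes of the reference annotation, 982 genes were shared where 48.2 were expected by chance (odds ratio 267, 2-sided Fisher's exact test, p below the smallest number that double precision can hold). That expectation takes all genes as equally likely to carry a peak, so it is likely too low as well. At the 1001 shared genes, the position of the highest peak differed by a median of 17 bp between the lists. It differed by 100 bp or less at 933 of them (93.2%), whereas random pairing of these genes gave a median of 999 bp. Overlapping peaks have close centres by definition, so these values follow largely from the overlap of peaks and are no separate evidence. Both lists may have been called against the same control library, which is not stated, and peaks that arise from that control would then be shared.

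Sites with strong signal were shared almost completely. When each list was split by score into 4 classes of nearly equal size, in the highest LL class 352 of 359 peaks (98.1%, 95% Wilson interval 96.0 to 99.1) overlapped an LD peak, and in the lowest class 151 of 358 (42.2%, 37.2 to 47.3) did. In LD the corresponding values were 387 of 402 (96.3%, 93.9 to 97.7) and 145 of 401 (36.2%, 31.6 to 41.0). The median score of shared peaks was 30 against 20 for unshared peaks in LL, and 56 against 39 in LD (permutation tests with 100000 resamples, 2-sided, both p = 1e-05, the smallest these can give). A shared peak must pass the calling threshold in both lists, so weak peaks would be shared less often even with the same binding. The fall over the classes and the difference in medians may therefore follow from the threshold. Across the 1069 shared peaks the log2 scores of the lists were correlated, with Pearson's r = 0.787 and Spearman's rho = 0.705 (permutation p = 1e-05 for both). These are values across peaks, which are not independent replicates. Scores ran higher in LD as a whole, with a median of 26 over all LL peaks and 48 over all LD peaks. A higher score in LD than in LL at a gene is thus no sign of stronger binding in LD.

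**Figure D2:**
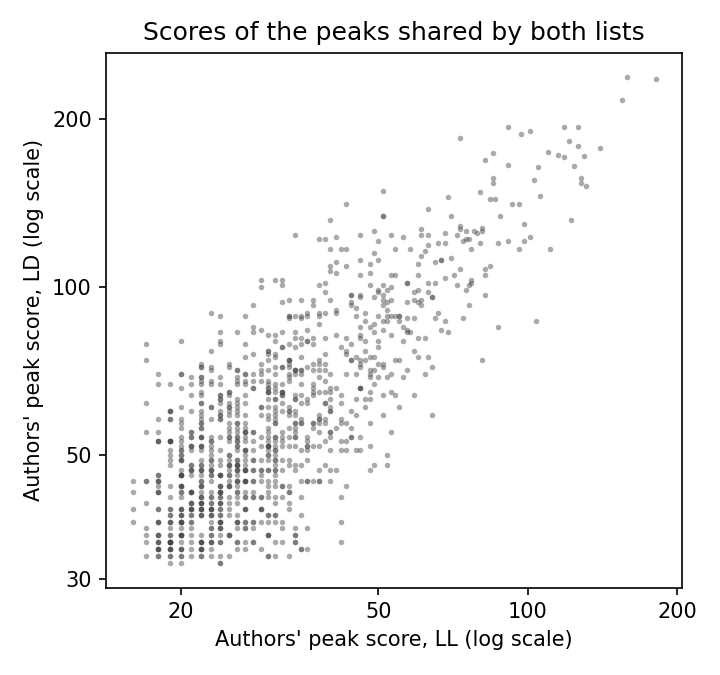
Authors' peak score in LL (x axis) and LD (y axis), both on log scales, with each point a peak found in both lists (n = 1069). Scores rise together (Pearson's r = 0.787 on the log2 scale).

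**Figure D3:**
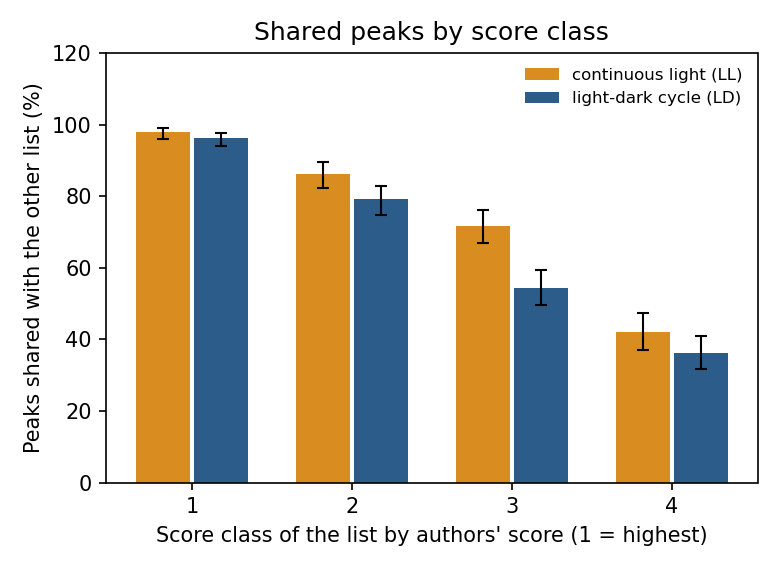
Percentage of peaks that overlap a peak of the other list, in 4 score classes of nearly equal size from the highest (1) to the lowest scores (4), in LL (orange) and LD (blue); error bars are 95% Wilson intervals. The percentage falls from 98.1% to 42.2% in LL and from 96.3% to 36.2% in LD.

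The peaks that overlapped no peak of the other list numbered 364 in LL and 538 in LD. Some of the strongest lay close to a peak of the other list. The highest LL-only peak (score 56) was a further peak at FKF1, 993 bp upstream of its TSS and 738 bp from the nearest LD peak. The next lay at AT2G29679 (score 54) and AT4G16146 (score 51), only 230 bp and 160 bp from LD peaks. They were followed by an intergenic peak (score 50) 1271 bp from the nearest LD peak. Its nearest gene was the pseudogene AT5G31821, whose TSS lay 8820 bp away. A peak at THIC (AT2G29630, score 49), a thiamine biosynthesis gene, lay 228 bp from an LD peak. In LD the highest was at the hexokinase gene HXK2 (AT2G19860; score 134, 248 bp upstream), 263 bp from an LL peak. AT2G29679 (score 95) and a peak at the 3' end of CBF1 (score 93, chromosome 4 from 13021070 to 13021194, 2353 bp from the nearest LL peak) came next. The remaining LD peaks lay at the ribosomal RNA gene AT3G41979 (scores 89 and 88), 654 bp and 469 bp from the nearest LL peaks. Control tags there were 10.4 and 9.8. Of the unshared peaks, leaving out 1 mitochondrial LL peak that has no LD peak on its chromosome, 341 in LL and 501 in LD had their centre more than 500 bp from any centre of the other list. In 301 and 450 of them the nearest gene also had no peak in the other list, and the highest-ranked of these stood at rank 247 in LL and 242 in LD. The LL peak lay beside a pseudogene, and the next outside rRNA genes, tRNA genes and pseudogenes stood at rank 301. No difference in genomic location of the unshared peaks passed the threshold: 207 of 364 (56.9%, 95% Wilson interval 51.7 to 61.9) and 303 of 538 (56.3%, 52.1 to 60.5) lay in the promoter-TSS category, a difference of 0.548 percentage points (Fisher's exact test, 2-sided, adjusted p = 1 over 7 categories). It was -0.0543 points with centres within 500 bp and -5.97 points among the upper 50% of each list (adjusted exact p = 1 and 0.978). The other categories had adjusted exact p from 0.975 to 1. The median absolute distance of unshared peaks to the TSS was 672.5 bp in LL and 611 bp in LD, a difference of 61.5 bp (permutation test, 2-sided, p = 0.488). Among the upper 50% of each list the difference was 228.5 bp (permutation p = 0.105). A weak peak that misses the calling threshold in one regime is counted as unshared, which limits these counts, the more so if the LL data held fewer tags.

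Genes of the circadian clock were bound far more often than other genes. Of 16 evening clock genes, 10 had an LL peak (62.5%, 95% Wilson interval 38.6 to 81.5; odds ratio 48.0, adjusted exact p = 3.48e-10) and 9 an LD peak (56.3%, 33.2 to 76.9; odds ratio 33.0, adjusted p = 7.53e-09). Of all nuclear genes 3.38% and 3.77% had a peak. All list tests were 2-sided Fisher's exact tests adjusted by Benjamini-Hochberg over 14 lists fixed beforehand and both regimes. JMJD5, COR27, FKF1 and COR28 had the highest LL scores (140, 131, 130 and 121) and LD scores of 178, 152, 172 and 183. LUX, BOA, ELF3, GI and CHE also had peaks in both lists. LKP2 had a peak in LL alone (score 29), and ELF4, ZTL and the 4 ELF4-like genes had none. At GI (AT1G22770) the peak scored 29 in LL (101 bp upstream) and 103 in LD (76 bp upstream). A peak assigned to the neighbouring AT1G22767, which the authors' annotation column places in the GI promoter, scored 106 in LL and 146 in LD. Since scores ran higher in LD in general, such pairs of scores are not read as changes in binding.

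Of 5 pseudo-response regulator genes, 2 had an LL peak (odds ratio 19.1, adjusted exact p = 0.0142) and 3 an LD peak (odds ratio 38.4, adjusted p = 0.00104). TOC1 scored 128 in LL and 157 in LD. PRR5 (AT5G24470) carried 4 peaks in each list, with highest scores of 98 and 130, and PRR7 was assigned a peak in LD (score 64). The LD peak at PRR7 overlapped an LL peak (score 35) that was assigned to the adjacent AT5G02811, so this site was bound in both regimes. Peaks in the PRR9 promoter were assigned to the adjacent AT2G46787 in both lists. With the gene of the annotation column the odds ratio was 115 in LL and 102 in LD, an alternative chosen after the data were seen. Of 14 morning clock genes, 4 had an LL peak (odds ratio 11.5, adjusted exact p = 0.00163) and 5 an LD peak (odds ratio 14.2, adjusted p = 0.000398). CCA1 itself (AT2G46830) carried a peak 214 bp upstream of its TSS in LL (chromosome 2, 19245379 to 19245537, score 82, 14.0-fold over control) and 252 bp upstream in LD (19245358 to 19245482, score 169, 14.9-fold). These peaks held 6.40 and 11.1 control tags, more than at 99.0% and 99.2% of other peaks outside rRNA genes and pseudogenes. RVE1, RVE7 and RVE2, which encode relatives of CCA1, had peaks in both lists (LL scores 61, 53 and 38). LHY, the closest relative of CCA1, had a peak in LD (score 41, 142 bp upstream) and none in LL. In its LD score class 219 of 402 peaks (54.5%) overlapped an LL peak, so an LL peak below the calling threshold is not excluded. RVE3, RVE4, RVE5, RVE6, RVE8 and LNK1 to LNK4 had none. Of 10 further clock-associated genes, TEJ and TIC had peaks in both lists (LL scores 22 and 20; adjusted exact p = 0.0480 in LL and 0.0562 in LD). The peaks at TIC did not overlap, with the LL peak 1258 bp from the nearest LD peak. The LL call of this list was lost among the upper 50% of peaks, where the odds ratio was 0, and under 3 further settings (odds ratios 4.92 to 7.15 against 7.16, adjusted exact p from 0.0523 to 0.216).

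**Figure D4:**
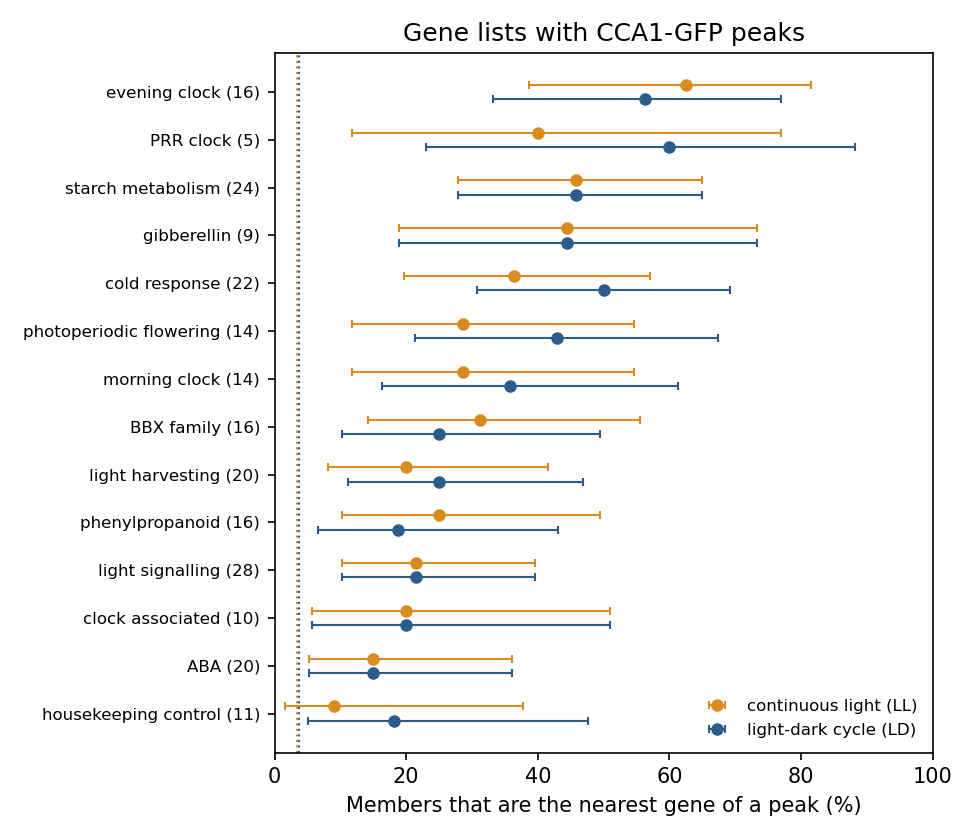
Percentage of the members of each gene list (number of members in brackets) that are the nearest gene of a peak in LL (orange) or LD (blue), with 95% Wilson intervals; dotted lines mark the percentage of all nuclear genes (3.38% and 3.77%). Evening clock genes reach 62.5% in LL and 56.3% in LD, and the housekeeping controls 9.09% and 18.2%.

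Light signalling, flowering and B-box genes were also bound. Of 28 light signalling genes, 6 had a peak in each regime (21.4%, 95% Wilson interval 10.2 to 39.5; odds ratios 7.83 in LL and 6.99 in LD, adjusted exact p = 0.000681 and 0.00104). They were the phytochrome-interacting factor genes PIF5 (LL score 104, LD score 87), PIF7 (34 and 89), PIF1 (25 and 46) and PIF4. The photoreceptor genes CRY2 (25 and 65) and PHOT1 were the others. The highest PIF1 peaks of the lists lay at different sites, but each LL peak at PIF1 overlapped an LD peak. No phytochrome gene had a peak, nor did HY5 or COP1. In LL the call was lost among the upper 50% of peaks (odds ratio 4.49, adjusted exact p = 0.103). Of 14 photoperiodic flowering genes, 4 had an LL peak (odds ratio 11.5, adjusted exact p = 0.00163) and 6 an LD peak (odds ratio 19.2, adjusted p = 2.62e-05). CDF1, which encodes a repressor of CO, scored 36 in LL (428 bp upstream) and 37 at the overlapping LD peak, while its highest LD peak (47) lay 36 bp upstream and overlapped no LL peak. SVP (25 and 46), CDF5 (24 and 64) and SOC1 (21 and 46) had peaks in both lists, COL1 (39) and CDF2 (34) in LD alone, and CO, FT and FLC in neither. These calls were lost among the upper 50% of peaks (odds ratios 4.48 in LL and 3.95 in LD, adjusted exact p = 0.229 and 0.246). Of 16 B-box genes, 5 had an LL peak (odds ratio 13.1, adjusted exact p = 0.000399) and 4 an LD peak (odds ratio 8.53, adjusted p = 0.00374). The LL odds ratio fell to 6.60 (adjusted exact p = 0.0218) with the gene of the annotation column, an alternative chosen after the data were seen. BBX22 (59 and 98), BBX28 (50 and 98), BBX29 (37 and 52) and BBX32 (19 and 53) had peaks in both, and BBX14 in LL alone (18). The list did not hold BBX8, COL5 and COL9, further B-box genes with peaks in both regimes.

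Cold-response genes had peaks more often than other genes. Of 22 members, 8 had an LL peak (36.4%, 95% Wilson interval 19.7 to 57.0; odds ratio 16.4, adjusted exact p = 1.62e-06) and 11 an LD peak (50%, 30.7 to 69.3; odds ratio 25.7, adjusted p = 9.72e-10). CBF1 (LL score 101, LD score 191), CBF3 (68 and 87) and CBF2 belong to a tandem cluster of transcriptional activators, in which a peak between genes can be assigned to either neighbour. ERD7 scored 63 and 138 and COR15B 57 and 83, and RAV1, ERD10 and COR413PM1 had peaks in both lists, those at COR413PM1 272 bp apart and not overlapping. KIN2 (62), ZAT12 (50) and GOLS3 (36) had LD peaks alone, though LL peaks below the calling threshold are not excluded.

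Starch metabolism genes were also bound, with the same 11 of 24 members in both regimes (45.8%, 95% Wilson interval 27.9 to 64.9; odds ratios 24.4 in LL and 21.8 in LD, adjusted exact p = 9.72e-10 and 2.33e-09). Synthesis was represented by the branching enzyme gene SBE3 (LL score 74, LD score 121) and the starch synthase gene SS4 (53 and 105). Breakdown was represented by ISA3 (45 and 89), DPE1 (34 and 59), GWD1, PWD, LSF1, PHS1, PHS2, BAM4 and AMY3. The peaks at PHS2 lay 222 bp apart and did not overlap. Of 20 light-harvesting genes, 4 had an LL peak (odds ratio 7.17, adjusted exact p = 0.00570) and 5 an LD peak (odds ratio 8.54, adjusted p = 0.00136). They were LHCB1.3 (52 and 99), LHCB1.4 (49 and 126), LHCB2.3 (38 and 69) and LHCB2.1 (20 and 42), with LHCA4 in LD alone (47). LHCB1 genes are near-identical copies. The LL peak at LHCB1.4 lay 212 bp upstream of its TSS, and the annotation column placed it in the promoter of LHCB1.5.

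Hormone and phenylpropanoid genes had peaks as well, with calls that depended on the setting. Of 9 gibberellin genes, the receptor genes GID1C (LL score 51, LD score 59) and GID1A (39 and 68) and the metabolic genes GA2OX1 (22 and 40) and GA3OX1 (22 and 34) had peaks in both regimes (odds ratios 23.0 in LL and 20.5 in LD, adjusted exact p = 0.000399 and 0.000553). The calls were lost when peaks from 1000 bp upstream to 500 bp downstream of the TSS alone were used (odds ratios 5.53 and 4.98, adjusted exact p = 0.213 and 0.216). Of 20 abscisic acid genes, CYP707A2 (34 and 48), ABI5 (34 and 52) and PYL5 (19 and 40) had peaks in both (odds ratios 5.06 and 4.51, adjusted exact p = 0.0347 and 0.0440). These calls were lost under 3 of 6 alternatives (adjusted exact p from 0.0620 to 0.0908 in LL and from 0.0738 to 0.104 in LD), with odds ratios of 3.87 to 6.49 in LL and 3.43 to 5.71 in LD. Of 16 phenylpropanoid genes, PAL2 (31 and 57), MYB90 (27 and 49) and the chalcone synthase gene CHS (26 and 59) had peaks in both and FLS1 in LL alone (19; odds ratios 9.56 in LL and 5.90 in LD, adjusted exact p = 0.00265 and 0.0263). They were lost with the gene of the annotation column (odds ratios 4.09 and 1.70, adjusted exact p = 0.108 and 0.459) and with TSS-proximal peaks (odds ratios 6.33 and 2.66, adjusted p = 0.0637 and 0.328). LD also lost its call against protein-coding genes (odds ratio 4.48, adjusted exact p = 0.0520). Of 11 housekeeping controls, UBQ10 had an LL peak (37) and UBQ10 (95) and EF1A (35) had LD peaks (odds ratios 2.86 and 5.68, adjusted exact p = 0.315 and 0.0646). With TSS-proximal peaks alone these controls passed the threshold in LD (odds ratio 8.86, adjusted exact p = 0.0399). Their LD odds ratio of 5.68 was above that of the abscisic acid list (4.51) and near that of the phenylpropanoid list (5.90). The controls' LD share of 18.2% had a wide 95% Wilson interval (5.14 to 47.7). It was also near the LD shares of light signalling (21.4%), B-box (25%) and light-harvesting genes (25%), whose intervals overlapped it. The LD calls of all these lists are thus not set apart from the controls.

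The lists did not separate the regimes. Of their 225 genes, 65 had peaks in both regimes, 3 (LKP2, BBX14 and FLS1) in LL alone and 9 (LHY, PRR7, COL1, CDF2, KIN2, ZAT12, GOLS3, LHCA4 and EF1A) in LD alone. These counts follow the nearest gene, and the LD peak at PRR7 overlapped an LL peak assigned to its neighbour. Among the 305 genes with a peak in LL alone and the 454 with a peak in LD alone, no list differed (Fisher's exact test, 2-sided, adjusted p = 1 for each of 14 lists, and 0 lists at an unadjusted p under 0.05). Cold-response genes had the lowest unadjusted exact p, with 0 LL-only and 3 LD-only genes (Fisher's exact test, p = 0.278). With 0 to 3 members per list bound in a single regime, these tests could not detect a difference between regimes.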

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

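Of the tests in this part, the comparison of CCA1 control tags with all other peaks was chosen after the values were seen, and the comparison with peaks of similar tag number before. The values below come from the control column and from the mitochondrial genome, which the gene-level comparisons do not use.

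The control library carried signal at the promoter of CCA1 itself. Control tags, scaled to the precipitated library, were 6.40 at the CCA1 peak in LL and 11.1 in LD, above 99.0% and 99.2% of other peaks outside rRNA genes and pseudogenes (the percentile in the lower list was 99.04). Strong binding sites mostly had fewer: the 20 peaks nearest in total tags had a median of 2.2 in LL and 3.3 in LD. In LD 0 of them reached the CCA1 value, which argues against a general effect of strong sites there. In LL 2 of them did, with up to 10.3 control tags, so the LL list does not argue against it. Both lists may rest on the same control library, which is not stated, so they may not be separate observations. A candidate explanation is that the CCA1-GFP transgene carries further copies of the CCA1 promoter, which would raise control tags there and part of the precipitated tags with them. A copy number difference of this region in WS-2 stays open and untested, no biological explanation was tested, and the fold over control at CCA1 (14.0 and 14.9) was below the median of the neighbours in tag number (40.6 and 48.4).

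The LL list held 1 peak on the mitochondrial genome, from 232994 to 233152, 31 bp upstream of ATMG00830. It had 24 tags (95% Poisson interval 15.4 to 35.7) against 5.30 control tags and was 4.54-fold over control, close to the lowest fold in the list (4.01). The LD list held 0 mitochondrial peaks.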

How the results depend on the processing

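Among the tests in this part, those with the gene of the annotation column, without repeat-associated peaks, with total tags as score and of GC content were chosen after the data were seen. Over 10 alternatives, 243 values were computed, of which 211 kept their direction and side of the threshold, or stayed within the interval or 1.5 times the count of the main value. The score differences between shared and unshared peaks and the correlation of scores (r from 0.760 to 0.787) were kept under each alternative run for them. The difference in distance to the TSS moved from 61.5 bp to between 49 bp and 228.5 bp and passed the threshold under none (permutation p from 0.105 to 0.502). The share of shared peaks followed the definition: it was 69.7% of LL and 62.2% of LD peaks when 50% of both peaks had to overlap, 68.8% of LD peaks with centres within 500 bp, and 71.3% of both lists when the same number of peaks was taken. Shared genes were then 73.4% of LL and 73.6% of LD genes. These shifts follow from the construction of the alternatives. The difference in promoter-TSS share of unshared peaks changed sign to -0.0543 percentage points with centres within 500 bp and to -5.97 among the upper 50% of each list (adjusted exact p = 1 and 0.978), and the cause was not tested. Lists past the threshold numbered 9 to 13 of 14 in LL and 10 to 13 in LD. Of the 25 list calls, 15 were kept under each alternative, among them those of the morning, PRR and evening clock, B-box, cold, starch and light-harvesting lists in both regimes. The clock-associated list reversed in LL to an odds ratio of 0 among the upper 50% of peaks, since none of its members lay there, and passed the threshold in LD with TSS-proximal peaks and with equal numbers of peaks (adjusted exact p = 0.0349 and 0.0461). No paired analysis was possible because the deposited lists pool the replicates and carry no replicate numbers. For the same reason no replicate could be left out. Also not run were the motif searches and their alternatives, the TSS-matched random placement, the assignment by reference TSS within 1000 bp and the background matched on upstream length, for lack of a genome sequence or gene strands. If both lists were scaled to the same total, which is not stated, the LL list rests on fewer tags by a factor of 2.17, which would limit the detection of weak sites in LL.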

Other observations

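The families, genes and tests in this part were chosen after the lists were seen, apart from the alternatives fixed before the data were examined. Members of several gene families had peaks, given here as counts alone. Fisher's exact tests were run on 17 families, but their p-values are left out because the families were chosen with the peaks in view. Of 13 DREB and CBF genes, 7 had a peak in both lists; beside the 3 CBF genes of the cold-response list these were DDF1, DREB2A, DREB2B and DREB2C. Of 26 CIPK genes, which encode kinases activated by calcium sensors, 5 had an LL peak and 6 an LD peak. Of 12 cytokinin response factor genes, CRF2, CRF3 and CRF4 had peaks in both lists. Of 12 JAZ repressor genes of jasmonate signalling, 3 had peaks in each list, with JAZ12 in LL and JAZ3 in LD. Auxin-induced SAUR genes had 9 of 80 members in LL and 6 in LD, and heat stress factor genes 4 of 21 in LL and 2 in LD. WRKY genes had 2 of 71 members in each list, and no SWEET gene of 17 had a peak.

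Some genes carried several peaks. AT1G40104 had 5 in each list, the rRNA gene AT3G41979 had 4 in LL and 6 in LD, and AT2G08986 had 4 and 5. No other gene had more than 4 in a list. The pseudogenes AT3G33055 and AT4G06700 had 3 in LL and 4 in LD. PRR5 had 4 in each list, from 2266 bp upstream to 89 bp downstream of its TSS in LL and from 2313 bp upstream to 80 bp downstream in LD. RVE1, RAV1, IDD5 and PIF1 had 3 in each list, those of RAV1 between 5993 bp and 1248 bp upstream in LL. NPR1, a regulator of immunity, and BPC1 had 3 in LL, and CDF1, AFP3 and DIN10 had 3 in LD. Among unshared peaks more than 500 bp from the other list at genes with no peak there, leaving out rRNA genes, tRNA genes and pseudogenes, the floral gene AP2 (LL score 36, chromosome 4 from 17397719 to 17397877, 2812 bp upstream) and the receptor kinase gene LYK4 (score 35) stood high in LL. ENODL2 (LD score 80, chromosome 4 from 13751965 to 13752089, 122 bp upstream), the channel gene MSL6 (score 74) and the jasmonate repressor gene JAZ3 (score 64) stood high in LD.

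Unshared peaks differed in base composition. The median GC content was 31.7% for the 364 LL-only and 34.1% for the 538 LD-only peaks, with 32.9% for shared peaks (LL-only minus LD-only -2.40 percentage points, permutation test, 2-sided, p = 1e-05). A different genomic location was argued against, since promoter-TSS peaks alone differed by -2.60 percentage points (permutation p = 1e-05, 207 and 303 peaks). GC-dependent recovery of fragments that differs between the libraries may contribute, since at shared peaks the log2 ratio of LD to LL tags rose with GC content (Spearman's rho = 0.140, p = 1e-05; Pearson's r = 0.0932, p = 0.00224). An effect of the light regime on CCA1 binding could give the same rise, so this test does not separate the explanations. Such an effect on where CCA1 binds stays open and untested, as each regime is a single pooled list.

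Peaks beside rRNA genes and pseudogenes (75 in LL and 68 in LD, of which 54 and 53 were shared) stood apart from other peaks. Their control tags were a median of 1.89 times those of the 20 other peaks nearest in total tags in LL, and 2.63 times in LD, which is consistent with repeat copies collapsed onto few reference copies. PCR duplicates stay open too: the median clonal fold was 1.09 in LL and 1.02 in LD, above the 95th percentile of other peaks (1.00 and 0.93) by at least 0.09. Collapsed repeats would raise the clonal fold as well, so these tests do not separate the explanations. The peak beside AT2G01023, with 18.3 control tags in LL and 38.3 in LD, was assigned to a gene for a hypothetical protein. It was not counted among the peaks beside rRNA genes and pseudogenes, and lists without those peaks still held it. No biological explanation was tested.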
